A study of Pseudomonas aeruginosa with 2 samples.

How the data were processed

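RNA from 2 cultures of P. aeruginosa PAO1 was measured on Affymetrix P. aeruginosa genome arrays, 1 array per culture. Per the labels' protocols and design text, overnight cultures were diluted 1:100 into 25 ml LB in 250 ml flasks, IAN (100 μg/ml) in 25 μl DMSO or the same volume of DMSO was added, and cells were shaken at 250 rpm and 37 °C for 5 h, then chilled and pelleted. Total RNA was purified on columns with a DNase digestion, 300 ng were converted to cDNA and amplified from random primers, and the fragments were labelled with biotin, per the labels' protocols. The groups were taken from the treatment label of each sample; the free-text description of the IAN sample repeats the wording of the control, while its title and treatment name IAN.

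The values deposited by the authors are linear probe-set intensities, 1 per probe set and array. They were summarised with MAS5, per the submitters' processing notes; MAS5 is Affymetrix's algorithm that combines matched and mismatched probes of a probe set and scales each array to a common level. Its version, background settings and detection calls are not given in the sources used here. From the values, the mean without the lowest and highest 2% of all 5896 probe sets was 500.2 on both arrays, so the deposited intensities had been scaled to the same level. Such scaling hides any change shared by most genes. No column of another sample was present in the table.

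Probe sets were sorted by name into PAO1 genes (5545), intergenic regions (199), sequences of other P. aeruginosa strains (117), transfer RNA (18), ribosomal RNA (3) and array controls (14), and those other than PAO1 genes stayed out of the comparison of genes. Gene names came from the locus tag in the probe-set name and the symbol that RefSeq gives it for PAO1 (assembly ASM676v1); 5504 loci matched and 41 did not, and genes without a symbol there are named by their locus tag. The platform annotation pairs 5500 probe sets with 1 gene symbol, none with several, and leaves 396 without one. Letter marks of the array maker in the probe-set name, taken here as marks for probes shared between sequences, are on 96 gene probe sets. The kinds of letter mark were not told apart, so shared probes are not established for each of these.

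The difference between the cultures was log2(IAN intensity) minus log2(DMSO intensity), as deposited, with no pseudocount. With 1 array per group there is no estimate of error, so no test was made. Genes were counted by size, at 2-fold or more, among those with a signal at or above the 25th percentile of gene probe sets (261 units for DMSO, 257 for IAN) on at least 1 array. For each of 25 lists of textbook pathways (474 loci, 467 with a probe set, no listed symbol contradicted by RefSeq) the median log2 ratio was set against 10000 random lists. These had the same size and were matched on 10 bins of mean log2 signal. As an alternative, it was set against 10000 random shifts of the list along the gene order with its spacing kept. The shifts were drawn with repeats, and short ones overlap the list itself. The percentiles describe these 2 arrays; they are not p-values.

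The lists, the filters, the random-list comparison and the rule for named genes were fixed before the data were examined. By that rule the text names the 12 genes with the highest and the 12 with the lowest ratio among genes at or above the median signal on either array, from each list up to 4 genes with the largest absolute ratio under the same filter, and 9 reference genes (lasR, lasI, rhlR, rhlI, mvfR, rpoS, fliC, pilA and oprF); genes outside it are pointed out where they occur. Alternatives were centring on the median, quantile normalization of both arrays, removal of a loess curve (span 0.4) of the ratio on mean signal, a pseudocount of 261 units, other filters, other fold thresholds, list means and list placement. Removal of the running median over the 250 genes to each side of a gene, and leaving out probe sets with shared probes, were chosen after seeing the data.

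Simulated arrays had the gene signals of the real ones and noise of 1 SD for all genes (5545 genes, 100 genes changed at each size). On them the count of genes at least 2-fold apart found 45% of genes changed 2-fold and 100% of genes changed 4-fold. It called 1 unchanged gene. A 2-fold change lies at the threshold, so it was bound to be found about as often as missed. A 4-fold change lay far past the noise. These 2 rates therefore follow from the settings and say little about the sensitivity of the real comparison. Of simulated unchanged lists of 20 genes 6.67% fell outside the central 95% of matched random lists, and 98.3% of lists of 20 genes shifted by 0.3 on the log2 scale lay above it. The simulated noise was independent between genes, and the simulated lists were scattered genes. Real ratios differed in spread with signal and were correlated between neighbours (r of 0.22). The simulated rates therefore may not hold for weakly hybridising genes or for lists of neighbouring genes. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.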

Results

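Transcript levels were measured in wild-type Pseudomonas aeruginosa PAO1, the standard laboratory strain of this opportunistic pathogen, on 2 Affymetrix P. aeruginosa genome arrays. One array held RNA from cells grown in suspension in LB for 5 h at 37 °C with 0.1 mg/ml IAN, and the other held RNA from cells grown in the same way with the solvent dimethyl sulfoxide (DMSO, 0.1%). IAN is taken here, from knowledge of the study, to be indolylacetonitrile, an indole compound made by plants; the sample labels give only the abbreviation. The series title names the effect of IAN on virulence as the question. Each group held 1 array, so no value below has a replicate error, no p-value was computed, and differences are given as sizes, with the percentile of each gene list's median among random lists. The number of arrays limits the precision of every value. Chromosome positions of genes are not given, since the genome build behind the array was not stated in the sources used here; genes are named by their PAO1 locus tag and symbol.

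The gene signals of the IAN and DMSO arrays were close to each other. Of 5545 probe sets for PAO1 genes, 97.3% lay within 1.5-fold and 99.7% within 2-fold between the arrays. The log2 signals correlated across genes with a Pearson r of 0.970 and a Spearman rho of 0.969; genes are not independent replicates. The log2 ratio of IAN over DMSO had a median of -0.0062 and an SD across genes of 0.25, and the middle 95% of genes lay between -0.50 and 0.50. With genes sorted by signal into 4 equal bins, this spread was 0.31 in the lowest bin and 0.21 in the highest, so a given fold carries less weight in weakly hybridising genes. The median gene signal was 409.8 MAS5 units on the DMSO array and 408 on the IAN array. Signals of PAO1 genes spanned a narrow range, with the 95th percentile 10.5 times the 5th on the DMSO array and 10.3 times on the IAN array. Ribosomal protein genes lay 1.96-fold and 2.09-fold above the median gene on these arrays, and a share of signal from DNA, which would draw every ratio toward 1, was not excluded, so the closeness of the arrays is not shown to be that of the transcripts.

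Of the 4354 genes that passed the low-signal filter, 7 were at least 2-fold higher and 1 was at least 2-fold lower in the IAN culture. The gene with the largest ratio was purU2 (PA5420), which encodes a formyltetrahydrofolate deformylase and gave 143 units with DMSO and 384 with IAN, a 2.68-fold difference. PA3501 was 2.39-fold higher (177 and 422 units), PA0204 2.14-fold, pntB (PA0196), a transhydrogenase subunit, 2.13-fold, PA0238 2.06-fold, PA1489 2.04-fold and PA3413 2.03-fold. The strongest signal among the 8 genes belonged to PA3413, with 1762 units in DMSO and 3568 in IAN. It alone of the 8 passed the filter on both arrays: the other 6 higher genes lay below the filter signal with DMSO, and pqsE lay below it with IAN. The single gene at least 2-fold lower was pqsE (PA1000), the last gene of the quinolone signal operon, which gave 425 units with DMSO and 207 with IAN, a 2.06-fold difference. With the running median along the gene order removed, an alternative chosen after seeing the data, its log2 ratio was -0.94 in place of -1.04, which is under 2-fold; PA0204 (0.995), pntB (0.99) and PA0238 (0.94) likewise came to lie just under 2-fold. Of these 8 genes, 5 (purU2, PA0204, pntB, PA0238 and PA1489) had too low a signal for the rule fixed for named genes and were named after their values were seen. At 1.5-fold, 52 genes were higher and 42 were lower in IAN, and at 3-fold there was none in either direction.

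**Figure D1:**
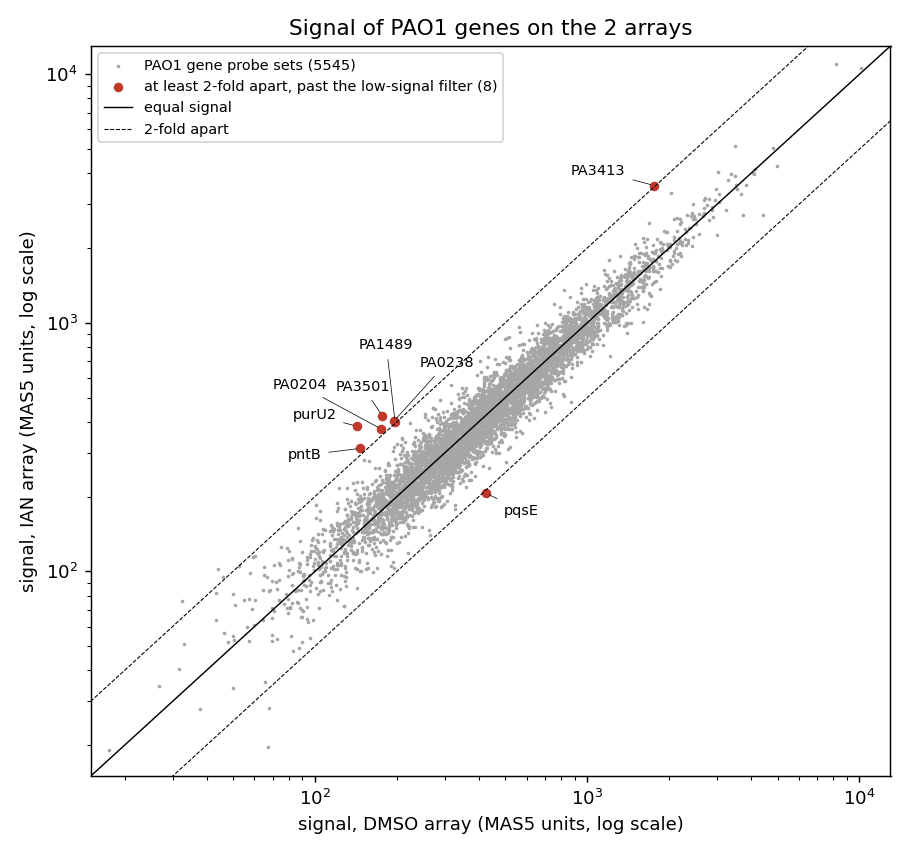
Signal of each of 5545 PAO1 gene probe sets on the DMSO array (x axis) and the IAN array (y axis), both in MAS5 units on log scales, with 1 array per group and no error bars. Points lie along the line of equal signal (Pearson r of 0.970 for log2 signals), and the 8 labelled red points are the genes at least 2-fold apart that passed the low-signal filter, 7 above and 1 below the line.

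Among genes with a signal at or above the array median on at least 1 array, the 12 with the highest ratios had log2 ratios of 0.75 or more. They were PA3501 (1.26), PA3413 (1.02), PA0239 (0.84), PA0193 (0.80), PA0422 (0.79), PA0653 (0.78), PA0522 (0.78), soxD (0.76), PA0119 (0.76), PA0203 (0.76), PA0206 (0.75) and PA0503 (0.75). The gene soxD (PA5417) encodes a subunit of sarcosine oxidase, and PA0203 and PA0206 belong to one gene cluster of a predicted ABC transporter. Of the 12 genes, 9 have locus numbers below PA1000, a part of the gene order that holds 18.02% of the genes measured. The 12 with the lowest ratios had log2 ratios of -0.67 or less. Besides pqsE (-1.04) these were flhF (-0.87), which places the polar flagellum, pilI (-0.87), a twitching motility gene, PA1832 (-0.75), PA2655 (-0.72), oprH (-0.72), an outer membrane protein, PA0822 (-0.71), PA3144 (-0.71), iscR (-0.69), the iron-sulfur cluster regulator, lolA (-0.68), pscL (-0.68), of the type III secretion cluster, and hemN (-0.67), an oxygen-independent heme synthesis enzyme. The probe sets of PA0522, PA2655 and PA3144 carry letter marks of the array maker. These were taken as marks for probes that may not be unique to 1 gene, so their values are uncertain. The loci PA0822 and PA3144 had no match in RefSeq, so the genes behind their probe sets are uncertain. A gene could pass the median filter through the array where it was high. PA3501 (177 units) and PA0119 (253) lay under the low-signal filter with DMSO, as did pqsE (207) with IAN.

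In the list of 8 regulators and signal synthases of cell-to-cell signalling (quorum sensing), 3 had a higher and 5 a lower signal with IAN, none reached 1.5-fold, and the median log2 ratio was -0.14, at the 5.46th percentile of 10000 random gene lists of the same size matched on signal. Within it the receptor gene lasR had a log2 ratio of -0.24, its signal synthase lasI 0.23, rhlR 0.05, rhlI -0.14, mvfR -0.25, rsaL 0.20 and qscR -0.36. In quinolone signal synthesis 7 of 9 genes were lower, with a median of -0.12 at the 8.96th percentile. Next to pqsE at -1.04, the other genes named from this list were pqsB (-0.18), pqsC (0.20) and pqsH (-0.24), and pqsA to pqsD, which precede pqsE in its operon, lay between -0.18 and 0.20. Of 17 phenazine genes 10 had a probe set under their locus tag. The 7 of them in the 2 nearly identical phenazine operons are marked for shared probes, so their values are uncertain and cannot be assigned to 1 operon. Of the 10, 8 were higher with IAN, among them the probe sets named phzG2 (0.29), phzB1 (0.27) and phzA1 (0.23), while that named phzE2 was at -0.27, and the median was 0.12 at the 93.98th percentile.

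Genes for extracellular products and secretion systems gave list medians near 0, with the exception of the type VI secretion cluster. Rhamnolipid and cyanide genes had a median of 0.04 (72.2th percentile) and a mean of -0.05, with rhlB at -0.57, rhlC at -0.11, hcnA at 0.08 and rhlA at 0.0038. The 20 genes for secreted enzymes, toxins and lectins had a median of 0.02 (63.6th percentile) and a mean of -0.03; the elastase gene lasB was at -0.29, aprI at 0.27, plcB at 0.24 and lipA at 0.19. Type II secretion genes had a median of -0.09 (19.2th percentile), with xcpQ at -0.27, xcpP at -0.22 and xcpT at -0.02. Of 39 type III secretion genes 17 were higher and 22 lower, with a median of -0.04 (22.6th percentile); pscL stood at -0.68, pscI at -0.37, exsB at -0.33 and the effector gene exoY at 0.49. In the HSI-I type VI secretion cluster, a contact-dependent system for injecting toxins into other bacteria, 13 of 18 genes were higher with IAN and the median log2 ratio was 0.27, a 1.21-fold difference. Named members were fha1 (0.50), ppkA (0.40), PA0078 (0.34) and hcp1 (0.32), and none of the 18 reached 1.5-fold. That median exceeded all 10000 matched random lists and stood at the 97.6th percentile of 10000 random shifts of the same arrangement along the gene order. Those shifts were drawn with repeats, and short ones overlap the cluster itself.

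Flagellar genes were lower with IAN as a list. Of 41 measured, 33 had a lower signal and 8 a higher one, and the median log2 ratio was -0.15, a level 0.904 times that of the DMSO culture, at the 0.08th percentile of matched random lists. The list was less extreme against the same arrangement of genes placed elsewhere on the chromosome, where it stood at the 4.01th percentile. Named members were flhF (-0.87), the rod gene flgG (-0.41), the export gene flhA (-0.36) and the stator gene motA, which was at 0.71 in the opposite direction. Flagellin, fliC, was at -0.21. Chemotaxis genes had a median of -0.08 with 12 of 18 lower (14.5th percentile), with PA1458 at -0.35, cheY at -0.25, aer2 at 0.21 and PA0178 at -0.18. Type IV pilus and twitching genes had a median of -0.05 with 19 of 30 lower (10.6th percentile); pilI was at -0.87, fimV at -0.62, pilF at -0.27, pilJ at 0.22 and the pilin gene pilA at -0.17. Of the 31 exopolysaccharide genes 15 were higher and 16 lower, with a median of -0.0012 that turned positive with other scalings of the arrays (56.5th percentile), and values of 0.52 for algF, 0.27 for algG, -0.22 for alg44 and -0.22 for pslA.

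Among iron uptake and transport lists, pyochelin genes had the highest median. Of 11 genes for this siderophore 10 were higher with IAN, and the median was 0.22 (98.01th percentile of matched lists), with fptA, its receptor gene, at 0.17 and pchD at 0.20. Most of the list hybridised weakly, with a median at the 6.27th percentile of gene signals, and the list stood at the 94.0th percentile when placed elsewhere along the gene order. It also lay inside the central 95% with quantile normalization, a pseudocount (96.2th percentile), weak members left out (96.8th), the list mean (94.6th) and the running median removed (96.0th). Pyoverdine genes had a median of 0.00089 (50.8th percentile), with pvdO at 0.43, pvdN at 0.28, pvdP at 0.19 and pvdA at 0.14. Multidrug efflux pump genes had a median of 0.06 (79.9th percentile), with mexA at 0.26, mexB at 0.15, mexC at 0.13 and oprM at -0.10. Porins of the OprD family had a median of 0.06 (83.05th percentile), with opdK at 0.38, PA0189 at 0.35, PA4179 at 0.29 and PA2760 at -0.28.

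Of 32 ribosomal protein genes 26 were higher, with a median log2 ratio of 0.17, a 1.12-fold difference, at the 99.98th percentile of matched lists. Named members were rpsN (0.51), rpsG (0.45), rplW (0.45) and rplC (0.41). All 9 measured ATP synthase genes were higher, with a median of 0.18 (98.3th percentile), among them atpH (0.42), atpA (0.36), atpF (0.32) and atpG (0.27). Both lists consist largely of neighbouring genes, and placed elsewhere along the gene order they stood at the 92.1th and 91.4th percentiles, inside the central 95%. With the running median along the gene order removed, the ATP synthase median was 0.05 (74.2th percentile) and the ribosomal protein median 0.14 (99.93th percentile). Denitrification genes had a median of 0.08 (93.05th percentile), with nosY at 0.31, PA0515 at 0.27, nirL at 0.17 and narI at -0.19. The arginine deiminase and anaerobic growth list had a median of -0.13 (9.31th percentile), with hemN at -0.67, anr at -0.17, arcB at 0.36 and arcC at 0.29. Tryptophan, kynurenine and anthranilate genes, the list closest to indole chemistry, had a median of 0.09 (94.6th percentile), with trpD at 0.40, antB at 0.26, kynU at -0.28 and kynA at -0.38.

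Stress list medians lay within the central 95% of matched random lists. Heat shock genes had a median of -0.13 (4.79th percentile), with hslV at -0.35, groES at -0.33, htpG at 0.34 and dnaK at 0.27. Oxidative stress genes had a median of -0.05 (31.9th percentile), with the superoxide dismutase gene sodM at -0.40, ahpC at 0.31, PA0848 at -0.11 and katB at -0.10. In the SOS list, the response to DNA damage, the median was 0.06 (81.7th percentile), with recA at 0.51, the SOS repressor gene lexA at -0.35, PA0670 at 0.19 and PA0669 at 0.13. The 39 R- and F-type pyocin genes had a median of 0.02 (62.4th percentile), with PA0628 at 0.59, PA0623 at 0.43, PA0615 at -0.37 and PA0641 at -0.34. The stationary phase sigma factor gene rpoS was at 0.05 and the major outer membrane protein gene oprF at 0.03. The oprF signals (245 units with DMSO, 250 with IAN) lay below the low-signal filter on both arrays, so its ratio is less certain. Over all 25 lists, 4 medians lay above and 1 below the central 95% of matched random lists. For lists of genes picked at random, 1.25 of 25 are expected outside it. Many listed genes are neighbours, and neighbours had correlated ratios, so the 5 are not shown to be an excess. Of the 5, 1, type VI secretion, was also outside the central 95% when placed elsewhere along the gene order, no more than the 1.25. A single listed gene, pqsE, was at least 2-fold apart.

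**Figure D2:**
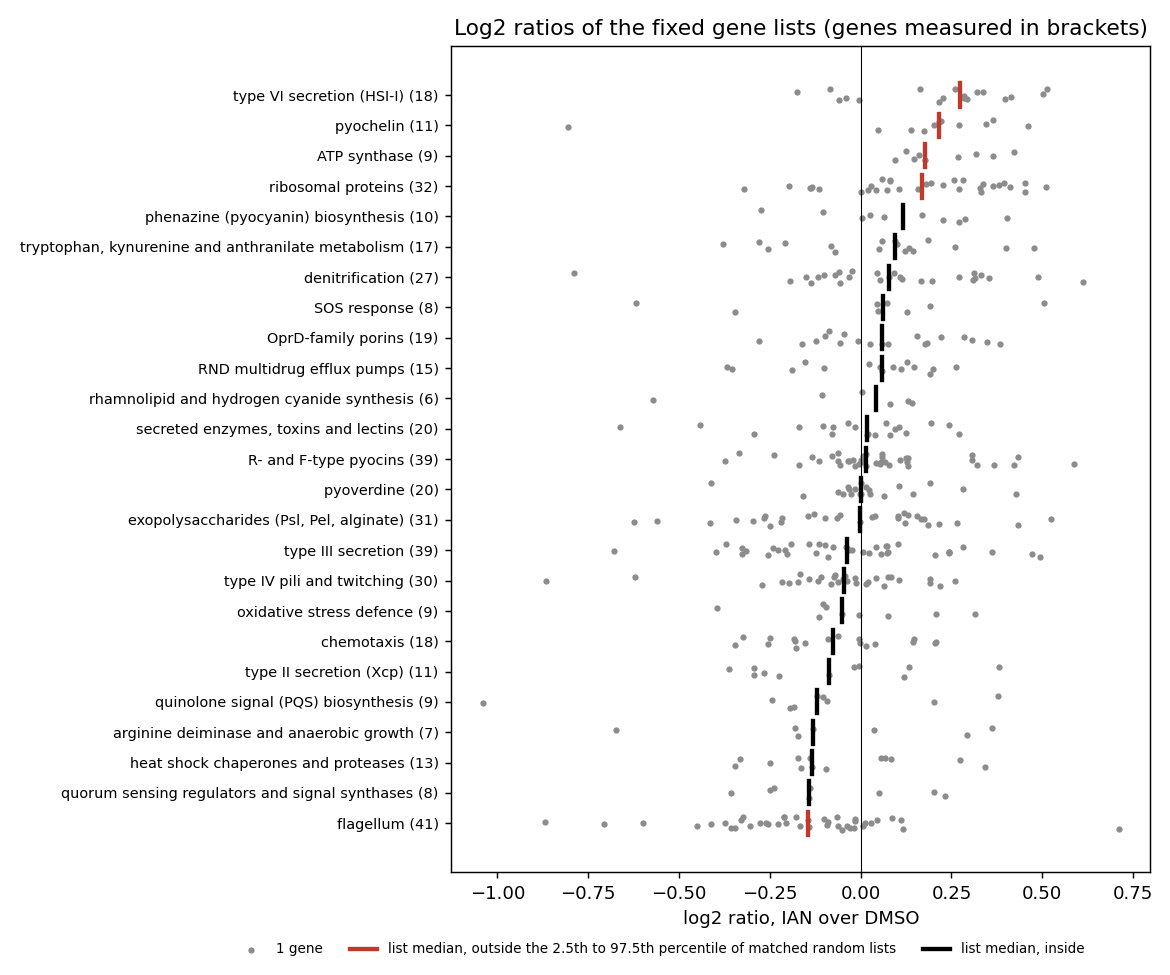
Log2 ratio of IAN over DMSO (x axis) for the measured genes of the 25 fixed lists (rows, with the number of genes in brackets); each grey point is 1 gene, each bar is a list median, and there are no error bars because each group held 1 array. Red bars mark the 5 medians outside the central 95% of matched random lists, from 0.27 for type VI secretion to -0.15 for the flagellum.

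The ratio also varied along the chromosome. The running median of the log2 ratio over the 250 genes to each side of a gene was highest at PA0032, at 0.14, near the replication origin, and lowest at PA0937, at -0.11. The ratio was lower with distance from the origin in both arms, with a Spearman rho of -0.27 across the 1994 genes up to PA2000 and of -0.17 across the 2557 genes from PA3000 onward; genes are not independent replicates. Neighbouring genes had correlated log2 ratios (r of 0.22), and the correlation was 0.17 for genes 10 places apart and 0.07 for genes 100 places apart. The regional difference is part of each value given above: with the running median removed, the type VI secretion median was 0.14 (99.1th percentile) and the flagellar median -0.09 (1.1th percentile), and the type III secretion median changed sign to 0.07. In the same setting, chosen after seeing the data, the chemotaxis median was -0.12 at the 2.02th percentile.

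**Figure D3:**
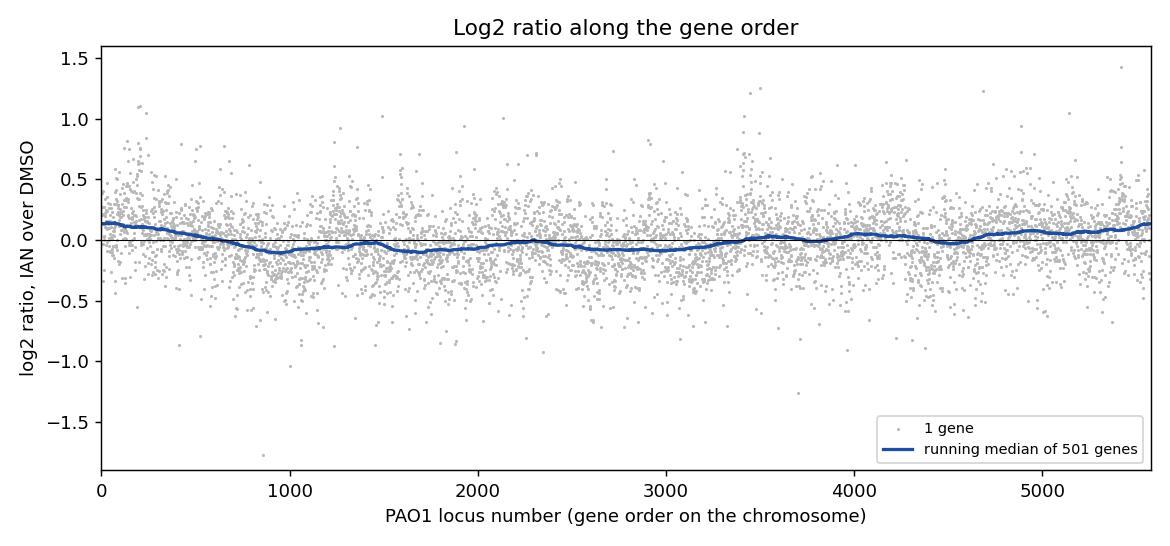
Log2 ratio of IAN over DMSO (y axis) against PAO1 locus number, the order of genes on the chromosome (x axis); each grey point is 1 gene and the blue line is the running median over the 250 genes to each side, with no error bars because each group held 1 array. The line is highest near the 2 ends of the axis, reaching 0.14, and lowest near PA0937, at -0.11.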

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

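The patterns below were found in these data, and the tests of the gene-order slope (before and after loess) and of the running median were chosen after the patterns were seen, while the bounds for each explanation were set before its deciding value was computed.

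The first pattern is the narrow range of signals. Signals of PAO1 genes spanned 10.5-fold from the 5th to the 95th percentile on the DMSO array, and 99.96% of them lay above the 95th percentile of probe sets for other strains. A high unspecific background left under every probe set in the deposited values is argued against, since the median PAO1 gene lay 103-fold (IAN) and 145-fold (DMSO) above the median of those probe sets. The background before the MAS5 summary cannot be judged from these values. DNA in the labelled material remains open: ribosomal protein genes lay 1.96-fold (DMSO) and 2.09-fold (IAN) above the median gene. This explanation needed values within 2-fold on both arrays, which the DMSO array met and the IAN array narrowly missed. Values over 4-fold on both arrays would have excluded it. Intergenic probe sets had medians 1.29 and 1.36 times the gene median, while the protocol includes a DNase digestion and compression of strong signals by the array could give a similar picture.

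The second pattern is the slope of the log2 ratio along the gene order. Signal-dependent scaling is argued against, since after removal of a loess curve on signal the slope kept 97.4% and 98.0% of its rho in the 2 arms, although mean signal sloped in the same direction (rho of -0.19 and -0.09). A difference in gene copy number near the replication origin, as between cultures growing at different rates, may contribute and remains open: both arms sloped in the same direction, with absolute rho of 0.27 and 0.166, but the smaller stayed under the 0.2 set in advance. Over bins of up to 250 locus numbers the median log2 ratio did not fall steadily from the origin. It was 0.16 for PA0001 to PA0250 and -0.11 for PA0751 to PA1000, but 0.0017 for PA2251 to PA2500, between the 2 arms. In the other arm it was 0.091 for PA5501 to PA5570, 0.098 for PA4001 to PA4250 and -0.15 for PA3001 to PA3250. Of 5544 rotations of the gene order, 11.7% gave slopes of the same sign, up or down, with absolute rho of at least 0.166 in both arms. Short rotations keep the observed slope, and those that move the origin across the chromosome reverse it, so this share cannot tell the slope from chance. A response of these regions to IAN remains open too, and was not testable with 1 array per group.

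The third pattern is the type VI secretion cluster HSI-I, with the highest list median (0.27). After removal of the running median it kept 51.6% of its size and stood at the 99.1th percentile, so the regional difference could account for part of it. Against the same arrangement elsewhere along the gene order it stood at the 97.64th percentile. This lay above the upper limit of the central 95%, but by less than the sampling error of the 10000 random shifts. So narrow a margin does not decide whether neighbouring genes anywhere share such a ratio. A biological response of the cluster to IAN stays open and has no replicate check.

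Outside the gene comparison, 1 probe set with a signal above the low-signal filter was at least 2-fold higher on the IAN array. This intergenic probe set, named for positions 224101 and 223454 (build not stated, not placed relative to genes here), gave 289 units with DMSO and 660.2 with IAN, 2.28-fold higher. Below that filter, where ratios are least certain, 3 probe sets for ribosomal and transfer RNA were listed after their values were seen. The signals of these probe sets are not shown to follow the amounts of these RNAs. The 16S ribosomal RNA probe set gave 45.4 and 209.7 units, 4.62-fold higher, and the 23S one 41.7 and 159 units, 3.82-fold higher, while the 5S one gave 3822 and 2642 units; the threonine transfer RNA probe set gave 31.1 and 63.0 units, 2.03-fold higher. Of the 14 array controls 3 were at least 2-fold higher, at signals up to 0.761 units, and of the 117 probe sets for other strains 38 were at least 2-fold higher and 20 lower, at signals up to 68.8 units.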

How the results depend on the processing

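The count of genes at least 2-fold apart (8; 7 higher, 1 lower) was 8 with median centring and 7 with quantile normalization or loess, all among the same 8 genes. It was 14 without the low-signal filter (11 higher, 3 lower), 3 with the filter at the median (2 higher, 1 lower), 94 at 1.5-fold (52 and 42), 0 at 3-fold (0 higher, 0 lower), 0 with the pseudocount (0 higher, 0 lower) and 4 with the running median along the gene order removed (4 higher, 0 lower), an alternative chosen after seeing the data in which pqsE was at -0.94, PA0204 at 0.995, pntB at 0.99 and PA0238 at 0.94, just under 2-fold; a pseudocount shrinks ratios by construction, and the fold threshold and filter change which genes can count. The count of lists outside the central 95% (5; 4 above, 1 below) was 1 (1 above, 0 below) when lists were placed elsewhere along the gene order, where flagellum, pyochelin, ribosomal proteins and ATP synthase moved inside; with the running median removed it was 2 above and 2 below, and the cause was not tested. Pyochelin also moved inside with quantile normalization, just below the upper limit, the pseudocount (96.2), the 25th percentile filter on members (96.8), the list mean (94.6) and the running median removed (96.0), where ATP synthase (74.2) moved inside too and chemotaxis (2.02) moved outside. The exopolysaccharide median, near 0, was positive under median centring, quantile normalization and loess. The SD of the ratios (0.25) was 0.25 with quantile normalization. None of 123 named genes changed sign under median centring, quantile normalization, loess or the pseudocount; xcpT and rhlA, both near 0, did with the running median removed, and the pseudocount, which draws every ratio toward 0, moved 17 by more than the SD of the ratios among genes of similar signal (10 bins). No paired analysis was possible because each group held 1 array. Low signals and the absence of replicates limit every ratio: in the lowest of 4 signal bins the SD was 0.31.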

Other observations

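Genes for the breakdown of glycine betaine and sarcosine, compounds that PAO1 can use as carbon and nitrogen sources, had higher signals with IAN along a run of neighbours. All 7 genes from PA5415 to PA5421 were above 0, with a median log2 ratio of 0.52 and a range from 0.33 to 1.42; soxB was at 0.52, glyA1, whose probe set is marked for shared probes, at 0.46 and soxA at 0.34. In a separate run, from PA0186 to PA0210, 23 of 25 genes were above 0 (median 0.52), and in another, from PA3407 (hasAp, a heme scavenger) to PA3414, all 8 genes were above 0 (median 0.67). These runs were chosen after their values were seen.

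The hypothesis that betaine and sarcosine degradation genes were higher as a group was tested on the 10 members that had not prompted it. Their median was 0.24, with 9 above 0, at the 99.84th percentile of matched random lists, at the 97.22th when placed elsewhere along the gene order and at the 98.63th with the running median removed. Of the 10, glyA1, soxB, soxA and fdhA lie in the run from PA5415 to PA5421 and are not independent of it, so these percentiles do not test the hypothesis. The 6 members outside the run, set apart after the values were seen, had a median of 0.12, with 5 above 0, at the 89.7th percentile of matched lists, the 82.5th when placed elsewhere and the 67.9th with the running median removed, all inside the central 95%, and the hypothesis remains open. The hypothesis that sulfate and sulfonate assimilation genes were higher as a group, prompted by PA3450 (0.59), was argued against: the 19 other members had a median of -0.0049 at the 49.02th percentile, with 9 above 0. Their log2 ratios ranged from -0.32 to 0.71. Close to PA3450 in locus number, PA3443 (0.71) and PA3446 (0.53) were high, while PA3444 (-0.10) and PA3445 (-0.04) were below 0. The median therefore speaks for the group as a whole and not for single members.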
